A study of Arabidopsis thaliana with 4 samples.

How the data were processed

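Leaf RNA of 4 samples was analysed, 2 taken before PBZ (time 0 h) and 2 taken 72 h after a root drench with 0.5 mM PBZ, grouped by the sample titles. Per the labels' protocols, total RNA was made into biotin-labelled cRNA for Affymetrix arrays. Per the submitters' processing notes, GCOS was used. Its version, its scaling target and other settings are not given in the sources used here. The deposited values are linear signals, the intensity of each probe set on 1 colour, and were used as deposited. Array medians of 19.2, 27.6, 32.5 and 27.1 differed by up to 1.69 times, so how the authors scaled the arrays to each other is unknown. Detection calls were not used here.

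Of the table, 64 control rows were left out, which left 16319 probe sets. The platform's annotation paired 9685 of them with 1 gene, 356 with several and 6278 with none listed, and the last are unnamed here. Of those with 1 gene, 9647 matched a locus of the TAIR10.1 reference, which was used for names only. The loci lie mostly on chromosomes 1 to 4, with 69 on chromosome 5, so the genes analysed are not a random part of the genome. Of 498 loci in gene lists fixed before the data were examined, 59 were in the table and 54 were tested, and 9 of 26 lists had at least 3 members. There were 12 genes to be named whatever their values, among them markers of SA response, senescence and chlorophyll breakdown. They were not analysed here, so the results on SA response and senescence rest on other genes. No gene of the chlorophyll breakdown list was in the table, so there is no result from a list on that process. A total of 8 list entries whose symbol the reference gives to another locus were left out.

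Signals were taken as log2(signal), with the 2 values of 0 set to 0.1, the smallest positive value. Probe sets in the lowest 0.25 by mean over all arrays (4080) were left out as dim. limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) compared the groups over the 12239 other probe sets, 2-sided, with Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual degrees of freedom and 27.2 prior degrees of freedom, so the error of each probe set leans on that of all probe sets. Only 2 arrays per group limit the precision. Folds are ratios of geometric means. Those written as "at least" set signals under 6.30, the lower quartile of all signals, to that value first, a choice made after the data were seen.

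Gene lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, the brightest, over 6725 genes, and adjusted over the 9 lists. Genes were named by a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among called probe sets of 1 gene whose groups do not overlap and whose brighter group lies above the median of all values, and up to 4 members of each list with the smallest p. It gave 71 genes, 32 of them called. A further 18 gene families were written after the files were seen and before any comparison, and 2 lists, the second endoplasmic reticulum list and the second photosynthesis list, after the first comparison but before the values of their members were seen. Of the families, 1 is counted in the adjustment and not reported here. The pattern of the cytochrome P450 family also took 2 cyclophilins, and a test without them was added after the data were seen. Family members were named after their values were seen.

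The fit was tested on simulated data with each probe set's mean, the spread of the fitted intensity trend and noise independent between probe sets. Over 12239 probe sets, after PBZ against before PBZ, it recovered 0 of 60 genes changed by a log2 of 1. It recovered 10 of 70 (14.3%) changed by 2 and 56 of 70 (80%) changed by 4, with 2 false calls. The simulated arrays did not differ in brightness and every probe set had the spread of the trend. These gene rates therefore do not cover errors of scaling or probe sets that vary more. With lists of 6 genes, the list test recovered 10 of 10 lists shifted by a log2 of 2 and called 0 of 30 unshifted lists. The simulated genes were uncorrelated, so these list rates do not cover lists of correlated genes or of fewer members.

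The alternatives were quantile normalization, centring each array on its median, no filter on dim probe sets or the lowest 0.5 left out, a pseudocount of 1.3 (the 10th percentile), the replicate number as a block, no intensity trend, shared probe sets left out, a test against a 1.5-fold change, each array left out in turn, and for lists an estimated correlation, fry and the mean over a gene's probe sets. The test with an estimated correlation rests on the 2 residual degrees of freedom, and no list or family passed it. A failure there therefore says little about any single list. With 2 arrays per group no other split of the samples was tested. Scan dates were not analysed here.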

Results

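Transcript levels were measured in leaves of Arabidopsis thaliana that were 5 weeks old, before and 72 h after a root drench with 0.5 mM probenazole (PBZ), a plant defence activator that the submitters applied to make the plants produce their own salicylic acid (SA). Rosette leaves 5 to 8 were sampled, which the submitters chose because these leaves yellowed most. Each of the 2 time points had 2 biological replicates, and each of the 4 RNA samples was hybridised to its own Affymetrix array. The median signal per array was 19.2 and 27.6 in the 2 samples before PBZ and 32.5 and 27.1 in the 2 samples after it. Of 16319 probe sets analysed, 12239 were bright enough to be tested, and 6799 of these were paired with 1 Arabidopsis locus. These probe sets are part of the array, and the other part was not analysed here. No untreated leaves of the later time were among the 4 samples, so each comparison is of leaves 72 h after the drench with leaves before it.

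The comparison asked which transcripts differed in leaves once the plants had been exposed to PBZ for 72 h. Genes of SA turnover and response, a putative chitinase and chaperones of the endoplasmic reticulum were among the rises. UGT76B1, a glucosyltransferase that acts on SA, had the largest fitted log2 change of the named genes, though both arrays before PBZ were under the floor described below. It rose from a signal of 2.2 ± 2.26 to 322 ± 87.8 (SD, 2 arrays per group; log2 change 7.71 ± 0.73 SE, limma adjusted p = 1.33e-08). CHI (AT2G43570), annotated as a putative chitinase, rose from 24.1 ± 6.65 to 1751 ± 880 (log2 change 6.11 ± 0.56, adjusted p = 7.61e-09). MSRB9, a methionine sulfoxide reductase, rose by a log2 change of 6.29 ± 0.73. The transcription factor WRKY53 rose from 28.6 ± 24.8 to 616 ± 269 (log2 change 4.69 ± 0.63, adjusted p = 6.23e-06), and the endoplasmic reticulum co-chaperone ATERDJ3B rose from 151 ± 79.5 to 3289 ± 1133 (log2 change 4.51 ± 0.50, adjusted p = 2.78e-07).

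The other 9 of the 12 genes with the largest fitted rises were AT4G00700, AT2G18690, AT1G26420, AT1G05340, AT4G39670, AT2G42360, AT1G78410, AT3G48640 and AT3G47480, with log2 changes between 5.68 and 7.23. For 10 of the 12 at least 1 of the 2 arrays before PBZ read under 6.30, the lower quartile of all signals, where a fold is poorly measured. Against that floor UGT76B1 was at least 50.2-fold higher, AT2G18690 at least 88.3-fold and MSRB9 at least 34.1-fold. CHI and AT3G47480 were above the floor on all 4 arrays, at 69.2-fold and 51.2-fold, so UGT76B1 cannot be ranked first by fold. Without after replicate 1, AT1G26420, AT2G42360 and AT1G78410 no longer passed the test (adjusted p from 0.132 to 0.495), and without after replicate 2 AT1G26420 did not (adjusted p = 0.0575).

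**Figure D1:**
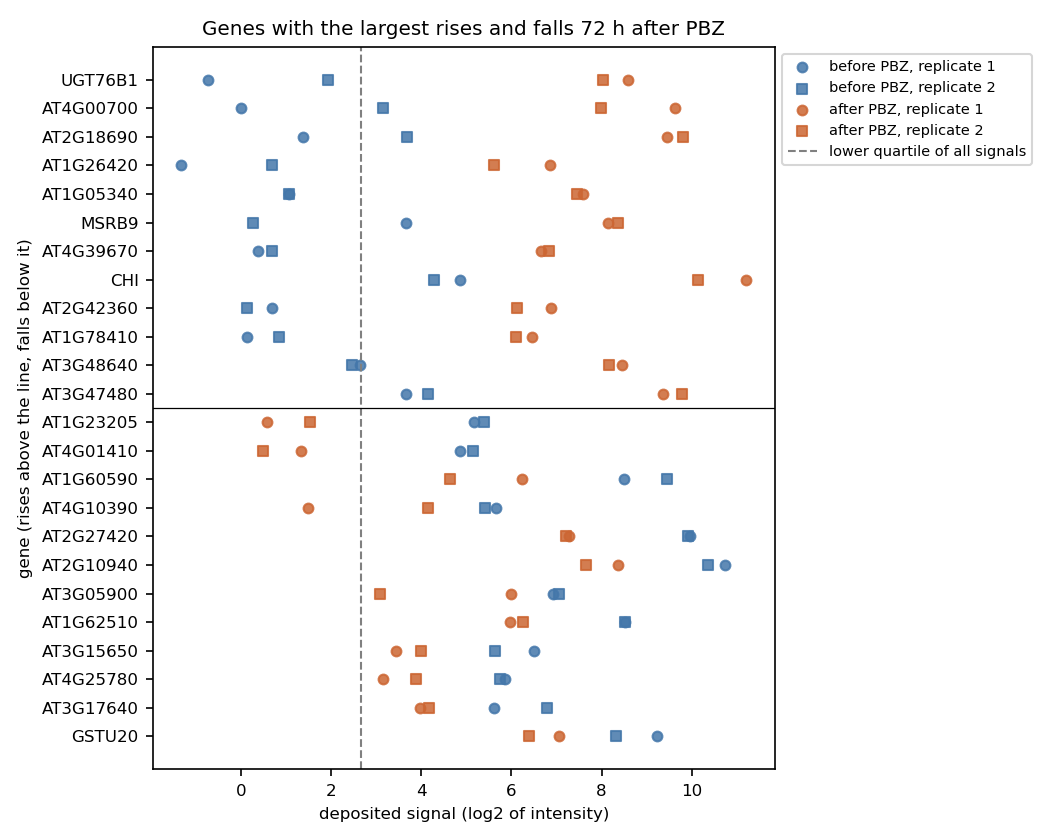
Deposited signal on a log2 axis in each of the 4 arrays for the 12 genes with the largest rises (above the black line) and the 12 with the largest falls (below it); blue marks are before PBZ, orange marks 72 h after it, and the dashed line is the lower quartile of all signals, 6.30. The rule that named these genes required both arrays of one group to lie above both arrays of the other. Many of the lower values lie left of the dashed line.

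Of the 12 largest fitted falls, AT1G23205 (log2 change -4.22 ± 1.00) and AT4G01410 (-4.10 ± 1.09) were under the floor of 6.30 on both arrays after PBZ, so they are known only to be at least 6.16-fold and 5.09-fold lower. Among brighter genes, AT1G60590 fell from 529 ± 238 to 50.2 ± 35.9 (log2 change -3.53 ± 0.60, limma adjusted p = 0.000193). AT2G27420 fell from 981 ± 24.5 to 151 ± 4.38 (log2 change -2.70 ± 0.51, adjusted p = 0.000663), and AT2G10940 from 1512 ± 267 to 267 ± 91.9 (log2 change -2.53 ± 0.49, adjusted p = 0.000848). GSTU20, a glutathione S-transferase, fell by 2.06 on the log2 scale (SE 0.56, adjusted p = 0.0223). AT4G10390, AT3G05900, AT1G62510, AT3G15650, AT4G25780 and AT3G17640 had log2 changes between -2.72 and -2.13, with 1 array after PBZ under the floor for AT4G10390 (at least 4.39-fold lower). Of the 12 falls, 7 no longer passed without before replicate 1 (adjusted p from 0.173 to 0.300), 6 without before replicate 2 (0.0526 to 0.163), 6 without after replicate 1 (0.132 to 0.608) and 6 without after replicate 2 (0.0522 to 0.814), and AT2G27420 alone passed with each array left out. Without an intensity trend 10 did not pass (0.0658 to 0.310), AT2G27420 among them.

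Over all probe sets, 653 were higher and 30 lower at 72 h (limma, 2-sided, adjusted p under 0.05). Of the 653, 320 had 1 locus, 556 rose more than 4-fold and 128 more than 16-fold. Of the 30, 15 had 1 locus and 21 fell more than 4-fold. The split depended on the scaling of the arrays: the median log2 change of all tested probe sets was 0.37 as deposited and -0.06 after quantile normalization, which gave 546 higher and 278 lower, and centring each array on its median gave 604 and 179. All 546 rises and 30 of the falls under quantile normalization were among those of the deposited scaling. The count of rises was 328 without before replicate 1, 1136 without before replicate 2, 217 without after replicate 1 and 335 without after replicate 2, and the count of falls 12, 25, 38 and 13 in the same order. The median log2 change was 0.07 without before replicate 1 and 0.62 without before replicate 2. With no intensity trend in the error model 157 rises and 8 falls passed, and against a 1.5-fold change 362 and 8.

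**Figure D2:**
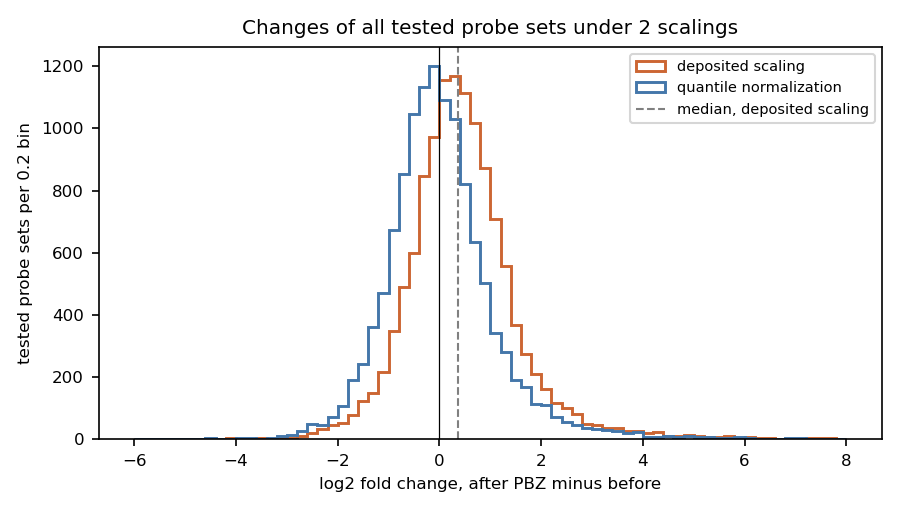
Number of tested probe sets (vertical axis) per bin of log2 fold change, after PBZ minus before (horizontal axis), with the deposited scaling (orange) and after quantile normalization (blue). The dashed line marks the median of 0.37 with the deposited scaling; after quantile normalization the median is -0.06.

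Log2 values correlated across probe sets at r = 0.888 between the 2 arrays before PBZ and 0.899 between the 2 after it, and at 0.806 to 0.848 between groups. These correlations are across probe sets, which are not independent replicates. The ratio of 3' to 5' signal of control transcripts, a sign of RNA integrity or of cRNA length, was read from both versions of the control probe sets, in the order before replicate 1, before replicate 2, after replicate 1 and after replicate 2. In the first version it was 26.5, 22.4, 64.8 and 22.6 for actin, 2.13, 4.87, 4.99 and 3.95 for GAPDH and 2.78, 3.41, 3.29 and 2.73 for ubiquitin. In the second version it was 2.54, 12.6, 12.9 and 10.6 for actin, 0.972, 1.68, 1.42 and 1.60 for GAPDH and 0.649, 1.91, 1.47 and 0.999 for ubiquitin. Before replicate 1 was thus lowest for GAPDH in both versions and for actin and ubiquitin in the second version. It was not lowest for actin or ubiquitin in the first version. A lower ratio is a sign of more intact RNA or longer cRNA, so these ratios do not mark before replicate 1 as the poorest array.

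Of the gene lists for SA, few members were measured here. UGT76B1 was the tested member of the SA turnover list and rose. Both tested members of the SA response list rose: WRKY53, and GRX480, a glutaredoxin of SA-responsive transcription, with a log2 change of 4.47 ± 0.66 (limma adjusted p = 2.91e-05; at least 14.8-fold). WRKY53 is also a member of the senescence list, whose other tested member, WRKY6, with 1 array before PBZ under the floor, had a log2 change of 1.60 ± 0.79 (adjusted p = 0.302). In the list of pattern and receptor immunity neither tested member passed, BIK1 at a log2 change of 1.85 ± 0.61 (adjusted p = 0.0726) and WRKY22 at 0.14 ± 0.72, though BIK1 passed when adjusted over the list alone (adjusted p = 0.00998) and without before replicate 2 (adjusted p = 0.00899). The direction of WRKY22 turned under quantile normalization, to -0.11.

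The list for folding and secretion in the endoplasmic reticulum stood above other genes. Of its 3 tested members 2 rose over all probe sets and 3 when adjusted over the list alone. These were ATERDJ3B, the calreticulin CRT1b, which rose from 221 ± 24.4 to 2133 ± 1127 (log2 change 3.16 ± 0.50, limma adjusted p = 6.56e-05), and BZIP60, a transcription factor of the unfolded protein response, with a log2 change of 1.75 ± 0.55 (adjusted p = 0.0571 over all probe sets, 0.00341 over the list alone). Their mean log2 change was 2.70 above the mean of the 6725 genes in the list test (camera adjusted p = 8.91e-07 over 9 lists). The preset correlation treats members as nearly independent, so this p rests on the spread across genes and does not measure that between replicates. With an estimated correlation, which no list passed, the list did not pass (adjusted p = 0.534), nor with fry (adjusted p = 0.095). CRT1b no longer passed without after replicate 1 (adjusted p = 0.0647) or without an intensity trend (0.0605), and BZIP60 passed over all probe sets without before replicate 2 (adjusted p = 0.0179).

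Both tested members of the auxin list rose: WES1, the conjugating enzyme GH3.5, by a log2 change of 3.57 ± 0.85 (limma adjusted p = 0.00752; at least 5.78-fold, with 1 array before PBZ under the floor), and IAA29, a repressor of auxin signalling, by 2.25 ± 0.60 (adjusted p = 0.0206). WES1 no longer passed without before replicate 2 (adjusted p = 0.107) or after replicate 1 (0.284), and IAA29 without before replicate 2 (0.0545), after replicate 1 (0.208) or after replicate 2 (0.167). Without the dim filter and without an intensity trend neither passed (WES1 0.105 and 0.211, IAA29 0.119 and 0.117), nor IAA29 with the replicate block (0.0597). In the list of reactive oxygen scavenging 1 of 4 members passed, the zinc finger factor STZ (ZAT10), which rose by a log2 change of 2.17 ± 0.57 (adjusted p = 0.0165) and which no longer passed without before replicate 1 (0.168), after replicate 1 (0.0961) or after replicate 2 (0.283), with the replicate block (0.0530) or without an intensity trend (0.144). GR1, TAPX and SAPX had log2 changes of 0.98 ± 0.47, -0.66 ± 0.52 and 0.07 ± 0.55, and SAPX was at -0.48 under quantile normalization. The list as a whole did not stand apart (camera adjusted p = 0.665).

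Members of the detoxification list went both ways. AT2G04070, a transporter of the MATE family listed as DTX4, rose by a log2 change of 2.85 ± 0.66 (limma adjusted p = 0.00597; 1 array before PBZ under the floor), while GSTU20 fell. UGT73B5, under the floor on both arrays before PBZ so that its size is poorly measured, and GSTU22 had log2 changes of 3.24 ± 1.09 (adjusted p = 0.0820) and 1.41 ± 0.72 (adjusted p = 0.316), and adjusted over the list alone 2 of the 5 members rose and 1 fell. The camera test gave an adjusted p of 0.665. AT2G04070 no longer passed without before replicate 1 (adjusted p = 0.184) or after replicate 1 (0.0720), and GSTU20 without before replicate 1 (0.270), after replicate 1 (0.132) or after replicate 2 (0.466). Without an intensity trend neither passed (0.154 and 0.189), nor AT2G04070 without the dim filter (0.0787). UGT73B5 passed without before replicate 1 (adjusted p = 0.0437), where its 1 array before PBZ read 1.4.

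The glucosinolate list stood below other genes with no member past the gene test. AT2G31790 (UGT74C1), UGT74B1 and BCAT4 had log2 changes of -1.31 ± 0.53, -0.80 ± 0.52 and -0.64 ± 0.47, a mean of 1.36 below that of all genes (relative mean -1.36, camera adjusted p = 0.0123). It did not pass with an estimated correlation (adjusted p = 0.630), without before replicate 2 (0.0699) or without after replicate 2 (0.152). Under quantile normalization AT2G31790 (adjusted p = 0.00532) and UGT74B1 (0.0439) passed the gene test as falls.

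Photosynthesis genes did not pass. The 2 tested members of the carbon fixation list, the Calvin cycle enzymes PRK and SBPASE, had log2 changes of -0.97 ± 0.36 (limma adjusted p = 0.130) and -0.65 ± 0.35 (adjusted p = 0.353). PRK passed when adjusted over the list alone (adjusted p = 0.0241) and under quantile normalization (adjusted p = 0.0188). Of 6 light reaction genes none passed. LHCB4.3, an antenna protein of photosystem II, was lowest, at a log2 change of -0.96 ± 0.49 and at -1.48 under quantile normalization, where it passed (adjusted p = 0.0132). LHCB4.2, PSBW and ATPC1 lay between -0.09 and 0.45, with ATPC1 at 0.04 and, after quantile normalization, at -0.15. The list test gave an adjusted p of 0.477 (camera, relative mean -0.54). For the 6 genes of chlorophyll synthesis the mean log2 change was 0.25, which lay 0.19 below that of all genes (relative mean -0.19, adjusted p = 0.665), so the mean and the test had opposite signs. HEMB1 was at 0.95 ± 0.51 and CHLM at -0.39 ± 0.45, and HEME1 and HEME2 were at 0.47 ± 0.57 and 0.40 ± 0.55, or -0.06 and -0.15 under quantile normalization.

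**Figure D3:**
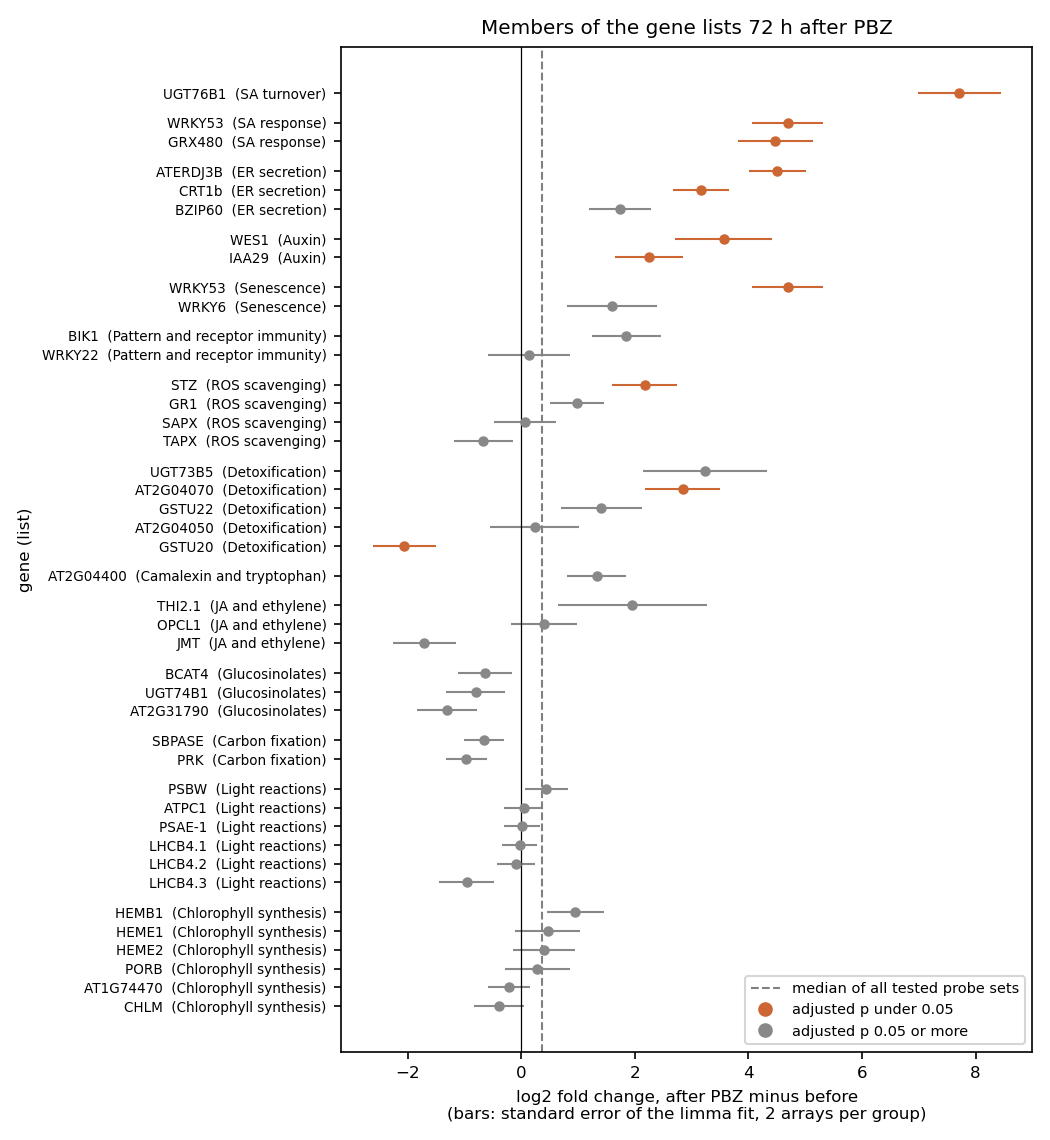
Log2 fold change of each tested member of 14 gene lists (horizontal axis), after PBZ minus before, with the standard error of the limma fit over 2 arrays per group; orange marks passed at an adjusted p under 0.05, and the dashed line is the median of all tested probe sets, 0.37. UGT76B1 stands highest at a fitted 7.71 and GSTU20 lowest at -2.06; the sign of WRKY22, SAPX, AT2G04050, OPCL1, HEME1, HEME2, PORB, PSAE-1 and ATPC1 turned under quantile normalization.

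The remaining pathway lists with a tested member gave no call over all probe sets. No member of the lists for SA accumulation, chlorophyll breakdown, cell division, or flavonoids and anthocyanins was tested. The lists therefore do not bear on those processes. In the list for jasmonate and ethylene the methyltransferase JMT had a log2 change of -1.70 ± 0.56 (limma adjusted p = 0.0708; 0.0144 adjusted over the list alone; 0.00403 under quantile normalization). THI2.1 and OPCL1 were at 1.95 ± 1.31 and 0.41 ± 0.58, the latter at -0.12 under quantile normalization and the former poorly measured, with both arrays before PBZ under the floor, and the list's camera direction was down while its median was 0.41 (adjusted p = 0.486). In the abscisic acid and cold list COR47 and COR15A were at -1.16 ± 0.51 and -0.94 ± 0.57, and LTI30 (1 array before PBZ under the floor) and COR15B at 1.49 ± 0.80 and 0.75 ± 0.56. The mean of that list was 0.04, its median -0.09 and its camera direction down (adjusted p = 0.486). COR47 passed under quantile normalization (adjusted p = 0.00709). AT2G04400, the indole-3-glycerol phosphate synthase of tryptophan synthesis, was at 1.33 ± 0.51 (adjusted p = 0.148; 0.0150 adjusted over the list alone). EXPA4 and EXPA8 of wall expansion were at -1.25 ± 0.66 and 0.68 ± 0.57, and EXPA4 passed without before replicate 2 (adjusted p = 0.0185) but turned to 0.07 without before replicate 1. The clock gene GI was at -0.57 ± 0.57.

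Markers of other leaf cell types and reference genes also stayed under the threshold. The guard cell factor FMA (FAMA) had a log2 change of 0.44 ± 0.60 and the phloem sugar transporter SWEET11 of -0.49 ± 0.42. No member of the epidermis or xylem marker lists was tested, so the lists do not bear on those cell types. Of 4 genes widely used as references, GAPC2, AT2G28390 and AT4G34270 were at 0.21 ± 0.34, 0.23 ± 0.56 and 0.42 ± 0.57, close to the median change of all probe sets, and AT4G26410 was at 1.17 ± 0.54 (limma adjusted p = 0.254). GAPC2 turned to -0.15 when each array was centred on its median, and AT2G28390 and AT4G34270 to -0.32 and -0.06 under quantile normalization (camera adjusted p = 0.665 for the list).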

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

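The tests of array brightness in this part, and the look at the control probe sets, were chosen after the main counts were seen; the test in the brighter 0.5 of probe sets was written before its result.

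Of the array's own 5 control probe sets for Arabidopsis GAPDH, which lay outside the comparisons, 4 stood higher on both arrays after PBZ than on both before it, relative to each array's median. For the 3' and middle sets the differences in log2 were 0.75 and 0.76, and for the second version's 3' and 5' sets 0.86 and 0.62. The first version's 5' set did not separate the groups (0.29), with before replicate 1 highest relative to its median. The probe set of GAPC2, a cytosolic GAPDH gene, was at a log2 change of 0.21 ± 0.34, which turned to -0.15 when each array was centred on its median. No explanation was tested.

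Far more probe sets rose than fell with the deposited scaling, 653 against 30. The 42 external control probe sets of bacterial and phage transcripts hold no plant gene. Their median log2 shift was 0.3965 (quartiles 0.116 and 0.493, 35 higher), close to the 0.37 of all tested probe sets. Array brightness could thus be part of the cause. These sets repeat a few transcripts, so they are not independent, and second-version bioC sets fell (-0.258 and -0.423). Without before replicate 1 the median change of all tested probe sets was only 0.07, yet rises still far outnumbered falls. That fit has 1 array before PBZ, so it does not settle the question. Array brightness as the whole cause cannot be told apart from the alternatives: after quantile normalization rises were 66.26% of calls, but at an unadjusted p under 0.05 there were 1219 rises and 1182 falls, and quantile normalization itself draws the array distributions together. In the 6119 brighter of the tested probe sets, where falls are easier to measure, quantile normalization gave 343 rises and 232 falls, a share of 59.65%. That is just inside the bound of 60% set beforehand, so dim probe sets whose falls cannot be measured may account for part of the surplus among calls. The margin is narrow and the same normalization was used, so this stays open.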

How the results depend on the processing

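The alternatives for families and their members were added after the files were seen. Of the 32 named genes that passed, 12 also passed under every alternative read for single genes, where they were tested. These were UGT76B1, AT4G00700, AT2G18690, AT1G05340, MSRB9, AT4G39670, CHI, AT3G48640, AT3G47480, WRKY53, GRX480 and ATERDJ3B. The stricter dim filter left out UGT76B1, AT1G05340 and AT4G39670, so they were not tested under it. The 1.5-fold test was run over all probe sets but read as counts only, so it is not among these alternatives. None of the 32 lost its call under quantile normalization, and none changed direction. Without an intensity trend 15 lost it, without the dim filter 8 and with the replicate block 4; of the 39 others 10 passed under some alternative. The arrays are few and dim probe sets lie near the floor, which limits all counts. Where no cause is given, the cause was not tested.

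The 653 rises and 30 falls became 546 and 278 under quantile normalization, 604 and 179 with each array centred on its median, 447 and 15 without the dim filter, 735 and 48 with the lowest 0.5 left out, 762 and 41 with the pseudocount, 157 and 8 without an intensity trend, 630 and 29 without shared probe sets and 362 and 8 against a 1.5-fold change. Leaving out 1 array, which leaves 1 arm with 1 array assumed to vary like the other, gave 217 to 1136 rises and 12 to 38 falls. Same-numbered samples showed no shared deviation from their group means (correlation across probe sets -0.064, 2 pairs). With only 2 pairs this cannot exclude a pairing. The replicate block gave 543 and 29.

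fry asks whether members changed at all and the main test whether they changed more than other genes, so a direction that differs between them is not a reversal of the main test. The endoplasmic reticulum list passed in every setting except an estimated correlation (adjusted p = 0.5344) and fry (0.09502). Leaving out 1 array gave 2.181e-10 to 9.984e-05. The glucosinolate list did not pass with an estimated correlation (0.63) or fry (0.2301), and ranged from 0.03019 to 0.152 with 1 array left out. With fry detoxification was at 0.03944 and chlorophyll synthesis pointed up (0.7619). Chlorophyll synthesis also turned up without the dim filter (0.9336). With the lowest 0.5 left out, the detoxification and jasmonate lists had too few members.

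Among the families, directions turned as follows (adjusted p): UGT with the lowest 0.5 left out (0.4575); ALDH under quantile normalization (0.6499), median centring (0.8649) and the lowest 0.5 left out (0.8504), and without before replicate 1 (0.5801) or after replicate 1 (0.7361), but not without the other arrays (0.6045 and 0.7667); ubiquitin enzymes under quantile normalization (0.9098), median centring (0.983), the pseudocount (0.9876) and no trend (0.954), and without before replicate 1 (0.7894) or after replicate 1 (0.7444). With fry BGLU (0.9427), SCPL and TET (0.786 each), SWEET (0.9595) and pseudogenes (0.786) pointed up, against no change. Pseudogenes turned with the lowest 0.5 left out (0.6409). SWEET turned without after replicate 1 (0.7444; 0.03802 to 0.7444 with 1 array left out), and TET without before replicate 2 (0.9458) or after replicate 1 (0.7444; 0.2939 to 0.9458).

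Of the 39 named genes that did not pass, 14 changed direction in some setting (log2). Under quantile normalization WRKY22 was at -0.1116, HEME1 at -0.0579, HEME2 at -0.1517, ATPC1 at -0.153, OPCL1 at -0.1187, SAPX at -0.4755, AT4G34270 at -0.06225 and AT2G28390 at -0.3196. With median centring WRKY22 was at -0.2231, ATPC1 at -0.3251, SAPX at -0.2983, GAPC2 at -0.153 and AT2G28390 at -0.1361. With 1 array left out the ranges were -0.1741 to 0.4608 for WRKY22, -0.05027 to 0.9405 for PSBW, -0.2694 to 0.08839 for LHCB4.2, -0.2797 to 0.3624 for ATPC1, -0.2239 to 1.035 for OPCL1, -0.2045 to 0.3409 for SAPX, -1.921 to 0.03886 for COR15A, -2.561 to 0.06841 for EXPA4, -1.172 to 0.04151 for GI, -0.002247 to 0.4292 for GAPC2 and -0.1575 to 0.6182 for AT2G28390.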

Other observations

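The families and the 2 second lists below were added after the files were seen, the second lists after the first comparison, and the members named were chosen after their values were seen; of the tests of explanations, that of growth and handling was written before its result and the others after.

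The UGT and cytochrome P450 families as wholes did not pass, but some members rose. In the UGT family 3 of 23 members rose and none fell: UGT76B1, UGT73D1 (log2 change 5.08 ± 0.79, at least 15.4-fold, with 1 array before PBZ under 6.30) and UGT87A2 (2.42 ± 0.56). Of 14 cytochromes P450 2 rose, CYP71B23 (4.28 ± 0.57, limma adjusted p = 5.67e-06) and CYP71B24 (2.94 ± 0.59). Others that rose were the tetraspanin TET8 (3.2 ± 0.52), the beta-glucosidase BGLU25 (2.63 ± 0.56), the ubiquitin ligase PUB24 (2.15 ± 0.57) and, of 6 glutamate receptor-like channels, GLR1.4 (3.29 ± 0.61), GLR2.8 (2.57 ± 0.71, at least 5.11-fold) and GLR2.7 (2.28 ± 0.62). Without after replicate 1 UGT73D1 (adjusted p = 0.0925), UGT87A2 (0.357), CYP71B24 (0.127), BGLU25 (0.111), PUB24 (0.336), GLR1.4 (0.109), GLR2.8 (0.453) and GLR2.7 (0.666) no longer passed. Without before replicate 1 UGT87A2 (0.101), CYP71B24 (0.0586), PUB24 (0.215) and GLR2.7 (0.299) did not pass, nor GLR2.8 without before replicate 2 (0.0803), nor PUB24 (0.106) and GLR2.8 (0.0868) without after replicate 2. GLR2.8 also lost its call under quantile normalization (0.0533), with median centring (0.0544) and without the dim filter (0.146), GLR2.7 without the dim filter (0.0625) and PUB24 with the replicate block (0.0548). CYP71B23 and TET8 passed with each array left out. Without an intensity trend TET8 did not pass (0.0694), nor did UGT73D1, UGT87A2, CYP71B24, BGLU25, PUB24, GLR1.4, GLR2.8 and GLR2.7 (0.0604 to 0.253).

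Of 6 autophagy genes measured, all of the ATG8 kind, ATG8E (log2 change 2.81 ± 0.67, 1 array before PBZ under 6.30) and ATG8D (1.89 ± 0.56) rose, and the family stood above other genes (relative mean 1.16, camera adjusted p = 0.0118 over 20 lists). With an estimated correlation the adjusted p = 0.818, without before replicate 1 it was 0.0626, and with the lowest 0.5 of probe sets left out it was 0.111. ATG8E no longer passed without before replicate 1 (adjusted p = 0.150) or after replicate 1 (0.149), and ATG8D without before replicate 1 (0.249), after replicate 1 (0.222) or after replicate 2 (0.457). ATG8D also lost its call under quantile normalization (0.0716), with the replicate block (0.123), without the dim filter (0.0679) and without an intensity trend (0.191), and ATG8E in the last 2 (0.0884 and 0.129). Families of wall acetyltransferases (TBL, 17 genes, relative mean -0.82, adjusted p = 0.0239), expansins and XTH enzymes (16 genes, -0.65, 0.0367) and IQ-domain proteins (6 genes, -0.98, 0.0367) stood below other genes with the preset correlation. With an estimated correlation none of the 3 passed (0.818 each). Below other genes with the preset correlation were also 184 pseudogenes (-0.22, 0.0367), a shift that ended under quantile normalization (0.863) and median centring (0.395), and the second photosynthesis list (15 genes, -0.56, 0.0467), of whose members none passed, and neither list passed with an estimated correlation (0.818 each). The expansin and XTH shift also ended under quantile normalization (0.182) and median centring (0.0714). Without the dim filter all 5 shifts ended (TBL 0.0542, expansins and XTH 0.0854, IQ-domain proteins 0.0712, pseudogenes 0.175 and second photosynthesis 0.110), and without an intensity trend all but TBL (0.0633 to 0.0770). Without shared probe sets the pseudogene and second photosynthesis shifts ended (0.0506 each). Leaving out 1 array ended each of these shifts: TBL without before replicate 2 (0.147) or after replicate 1 (0.116), expansins and XTH without before replicate 1 (0.372) or after replicate 1 (0.532), IQ-domain proteins without before replicate 2 (0.182) or after replicate 2 (0.294), pseudogenes without before replicate 1 (0.271) or after replicate 1 (0.464), and the second photosynthesis list without before replicate 2 (0.213), after replicate 1 (0.129) or after replicate 2 (0.117). In the TBL family TBL26 fell by 1.7 on the log2 scale and TBL35 rose by 2.13, but TBL26 did not pass without before replicate 1 (adjusted p = 0.0651), after replicate 1 (0.275) or after replicate 2 (0.229), nor TBL35 without before replicate 1 (0.284), after replicate 1 (0.442) or after replicate 2 (0.141). TBL35 also lost its call under quantile normalization (0.0536), with median centring (0.0536) and with the replicate block (0.0962), and both genes lost it without the dim filter (TBL26 0.0564, TBL35 0.177) and without an intensity trend (0.218 and 0.175). The WRKY and glutamate receptor-like families had camera adjusted p = 0.0467 and 0.0475 only with the 2 second lists added. Over the 18 families alone both were at 0.0550, so neither is a call. The second photosynthesis list, at the same 0.0467 as WRKY and added after the first comparison, is not taken as a call either.

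The other families reported gave no call: UGT (camera adjusted p = 0.281), cytochrome P450 (0.274 over 14 genes, or 0.336 as first tested with 2 cyclophilins), GST (0.281, 1 of 10 fell), bZIP (0.479), BGLU (0.336), SCPL (0.602), SWEET (0.336), ALDH (0.976), TET (0.602) and ubiquitin enzymes (0.976).

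The rise of the 3 endoplasmic reticulum genes of the fixed list had a mean log2 change of 3.14. Array brightness as its source is argued against by a mean of 2.632 after quantile normalization. A differing RNA integrity of before replicate 1 is argued against by a mean of 2.825 without that array. Growth and handling over 72 h without PBZ cannot be told apart from PBZ, with 0 arrays of untreated leaves at 72 h. A hypothesis is that genes of the wider secretory pathway moved with them. Of 12 such genes chosen without their values, SEC22 (2.12 ± 0.51), DER1 (2.42 ± 0.55) and ATERDJ2B (2.44 ± 0.58) rose. The list stood above other genes (relative mean 0.97, camera adjusted p = 0.001405), which goes with the hypothesis. With an estimated correlation the adjusted p was 0.818, but no list or family passed that test, so it cannot decide. The hypothesis stays open. SEC22 no longer passed without before replicate 1 (adjusted p = 0.117), after replicate 1 (0.0864) or after replicate 2 (0.390), DER1 without after replicate 1 (0.118) or after replicate 2 (0.152), and ATERDJ2B without before replicate 1 (0.0580) or after replicate 1 (0.370). Without an intensity trend SEC22 (0.193), DER1 (0.0915) and ATERDJ2B (0.135) did not pass.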
